A study of Mus musculus with 2 samples.

How the data were processed

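ATAC-seq was done on 2 biological replicates of the mouse cell line G1E, 50000 cells each, and both replicates form 1 group. Nothing in the labels says whether the replicates came from separate cultures, and every p-value describes these 2 libraries. Per the labels, the genome build is mm10. The reads were not used here. The authors deposited peak lists for each replicate and for both together, derived from the alignments and, for the thresholded lists, a further file of unstated content, per the submitters' notes on the files. The aligner, the peak caller and their versions are not given in the sources used here, and neither is the handling of reads that align in several places. Each listed peak has a signal value, the deposited enrichment value of the peak as the authors' peak caller gave it, and a −log10 p value, also as deposited. The deposited signal values are not scaled between libraries, and were used only to describe, rank or filter regions within a list. Percentiles of signal are ranks within a replicate's own list.

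The main lists were the per-replicate lists that the authors thresholded by the irreproducible discovery rate, which measures how well peaks rank alike in repeated samples. They held 26083 and 27810 summits. Overlapping or touching intervals were merged into regions, each with the summit and signal of its strongest peak, which left 21194 and 22620. Peaks on unplaced scaffolds were left out. The authors' more lenient per-replicate lists held 35229 and 39290 regions and were an alternative. Replicate values were set side by side in the authors' between-replicate list, of which 41485 regions were used, and 19075 of them passed an IDR of 0.05. Its unnamed columns were assigned to replicates by values equal to those of the replicates' own lists, 36667 for replicate 1 and 39480 for replicate 2. A further 2 lists of the series were not used. Since peak lists give no read totals, the depth is unknown, and a region missing from a list cannot be read as closed.

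Positions were compared with GENCODE M21, which uses the same build. A promoter region lies within 1000 bp of a start site of any transcript of a protein-coding gene, and a distal region lies over 1000 bp from the start sites of genes of every biotype. Overlap of replicates required 1 bp and was set against 100 random placements on the same chromosomes outside assembly gaps. Before the data were examined, 16 gene lists were fixed: hemoglobin and heme synthesis, red cell membrane and surface, erythroid transcription factors and cofactors, stem and progenitor, megakaryocyte and platelet, mast cell and basophil, granulocyte and macrophage, lymphoid, cytokine receptor signalling, embryonic stem cell, hepatocyte, neuron, fibroblast, endothelial, ribosomal proteins and cell cycle. They held 317 matched entries, and 1 further symbol, Ahsp, matched no protein-coding gene. Erg is in 2 lists.

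For each list and replicate, members with a promoter region were compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists. A list was called where the adjusted p was under 0.05 in the same direction in both replicates. As an alternative, each list was set against 10000 random lists matched on the promoter CpG observed to expected ratio in 20 bins. For neighbourhoods, distal regions present in both replicates within 50 kb of the gene's outermost 5′ end were counted, and the list's median was ranked among the medians of 10000 random lists of the same size. Random lists tied with that median counted 0.5 each in its percentile, and lists with a percentile of at least 97.5 were counted. Motif consensus strings for 20 motifs were matched exactly on either strand in 200 bp around each summit and in control windows 2000 bp away and outside every listed region. Every SP1 match is also a KLF1 match, and every NF-E2 match is also an AP-1 match, so these motifs are not independent. Promoter and distal regions were tested apart by two-sided Fisher's exact tests, adjusted over 20 motifs and 2 classes, and the distal and promoter shares were also tested against each other. Log2 ratios of shares had 0.5 added to each count of matches and 1 to each number of windows.

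Named genes followed a rule fixed in advance. It took, for each list, the 2 members with the highest mean percentile of signal at a promoter region in both replicates and the first 2 in alphabetical order with none in either. It further took 20 fixed blood loci, the 5 strongest promoter and the 5 strongest distal regions, and the 10 genes with the most distal regions. Not every gene under the rule is reported here. Other list members named in the text were chosen after their values were seen. Alternatives were the unmerged summits, the lenient lists, a Pearson correlation of log2 values, the stronger 50% of regions, leaving out each replicate, promoter windows of 500 and 2000 bp, other sets of start sites, a reciprocal overlap of 50%, summits within 100 bp, neighbourhoods of 20 and 100 kb, motif windows of 100 bp, and GC-matched or shuffled control sequence. Alternatives added after the data were seen were the authors' list over both replicates, motifs without the strongest 1% of regions, means in place of medians, the heme list without its globin genes, promoter regions shared between replicates, and the mast cell list without members whose neighbourhoods overlap.

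The tests were checked on simulated data. With the 21938 protein-coding genes and 100 simulations, 99.7% of lists set to 90% of members and 94.3% of lists set to 5% were called in the set direction, and 0.5% of unchanged lists were called. A GATA match planted in 29.2% of 5000 random windows was recovered as 28.6%, and an overlap set to 79.7% of 21194 regions was recovered as 80.1%. In the simulations every unchanged gene had the same probability of a promoter region, and summit and control windows had the same even base composition. They therefore do not give the rate of false calls where promoter CpG content or base composition differs, as in the real data. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and pysam 0.24.0, matches to the mitochondrial genome used blastn 2.17.0+, and figures were drawn with matplotlib 3.10.9.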

Results

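Accessible chromatin was mapped by ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in the mouse cell line G1E. G1E cells are erythroid progenitors that lack the transcription factor GATA1 and stop maturing before terminal red cell differentiation. The series held 1 group with 2 biological replicates, each made from 50000 cells, so no comparison between conditions was possible. The data were the authors' peak lists, which hold no read totals, and the depth of each library is therefore unknown. The questions the design addresses are which regions were open in both replicates, which genes lie at or near them, and which sequence motifs they carry.

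Replicate 1 had 21194 accessible regions and replicate 2 had 22620, a mean of 21907 ± 1008 (SD, n = 2). They covered 9.53 Mb and 10.3 Mb, with a median width of 420 bp in both. Of the regions of replicate 1, 17776 (83.9%) overlapped a region of replicate 2, and 17662 (78.1%) of those of replicate 2 overlapped replicate 1. Random placement of the other replicate's regions on the same chromosomes gave at most 0.981% and 0.889% in 100 placements. Joined over both replicates there were 25799 regions, of which 17425 were in both, among them 8538 at promoters and 8227 distal to every annotated start site.

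Regions listed in 1 replicate alone were weaker and more often distal. In replicate 1, 3418 regions (16.1%) had no partner, and their median percentile of signal was 16.6 against 57.7 for shared regions. In replicate 2, 4958 regions (21.9%) had none, with a median percentile of 20.1 against 60.2. Promoters made up 24.3% of the unshared and 49.3% of the shared regions in replicate 1 (two-sided Fisher's exact test, p = 2.46e-168), and 29.6% of the unshared and 8656 of 17662 shared regions in replicate 2 (exact p = 1.38e-133). The more lenient list of the other replicate held 61.4% and 50.2% of the unshared regions, which left 6.22% and 10.9% of all regions without a counterpart in either list. Across 41485 regions that the authors paired between replicates, the −log10 p values of the 2 libraries had a Spearman correlation of 0.852. Regions are not independent replicates, so no p is given for it, and the exact p values over regions or summits, here and below, hold for these lists alone and treat regions as independent.

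Promoters of protein-coding genes held 45.0% ± 0.365 (SD, n = 2) of the regions, 9.48 times the 4.75% of randomly placed regions. Introns away from any start site held 28.0% ± 0.178 and intergenic sequence 20.6% ± 0.0452, below the random shares of 39.4% and 49.8%. Promoter regions were stronger and wider than distal ones, with a median signal of 9.32 against 7.41 and a median width of 450 bp against 395 bp in replicate 1, and 10.4 against 8.06 and 468 bp against 386 bp in replicate 2. Of 21938 protein-coding genes, 8889 and 9244 had a promoter region, 41.3% ± 1.14 (SD, n = 2), and 8571 had one in both replicates, although not the same region in 83 of them. The promoter share followed the threshold and the window, from 32.5% with the authors' lenient lists to 55.1% in the stronger 50% of regions.

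Most members of the erythroid gene lists had a promoter region in these Gata1-deficient cells. A promoter region was present at 92.5% ± 3.54 (SD, n = 2) of the erythroid transcription factors and cofactors, at 77.5% ± 3.54 of the genes for red cell membrane and surface proteins, and at 71.1% ± 3.72 of the hemoglobin and heme synthesis genes. Klf1, Tal1, Lmo2, Ldb1, Zfpm1, Gfi1b, Nfe2 and Bcl11a were among the 18 factors with a promoter region in both replicates. Nfe2, a subunit of the NF-E2 factor of the globin loci, had the strongest one (chromosome 15, 103258229 to 103258790; signal 13.7 and 15.7), followed by Tcf3, which encodes the E proteins that pair with TAL1 (signal 12.6 and 14.9). E2f2 was the member with none in either replicate, and Mafg had one in replicate 2 only.

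In the heme list, Slc25a37, the mitochondrial iron importer mitoferrin 1, led with a signal of 13.9 and 16.9, at the 91.9 mean percentile of all regions. The adult alpha-globin gene Hba-a2 followed with 13.1 and 17.5. Regions were also present in both replicates at the heme enzymes Alad, Uros, Urod, Cpox, Ppox and Fech and at the transferrin receptor Tfrc. The 5 members without a promoter region in either replicate were Alas2, Hba-x, Hbb-bh1, Hbb-bt and Hbb-y, that is 4 globin genes and the erythroid form of the first enzyme of heme synthesis. In the membrane list, 15 of 20 genes had a region in both replicates, among them Slc4a1, Epb42, Ank1, Sptb and Rhag. Trim10, a gene of the tripartite motif family, had a signal of 10.2 and 15.7. Aqp1 and Dmtn had none.

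**Figure D1:**
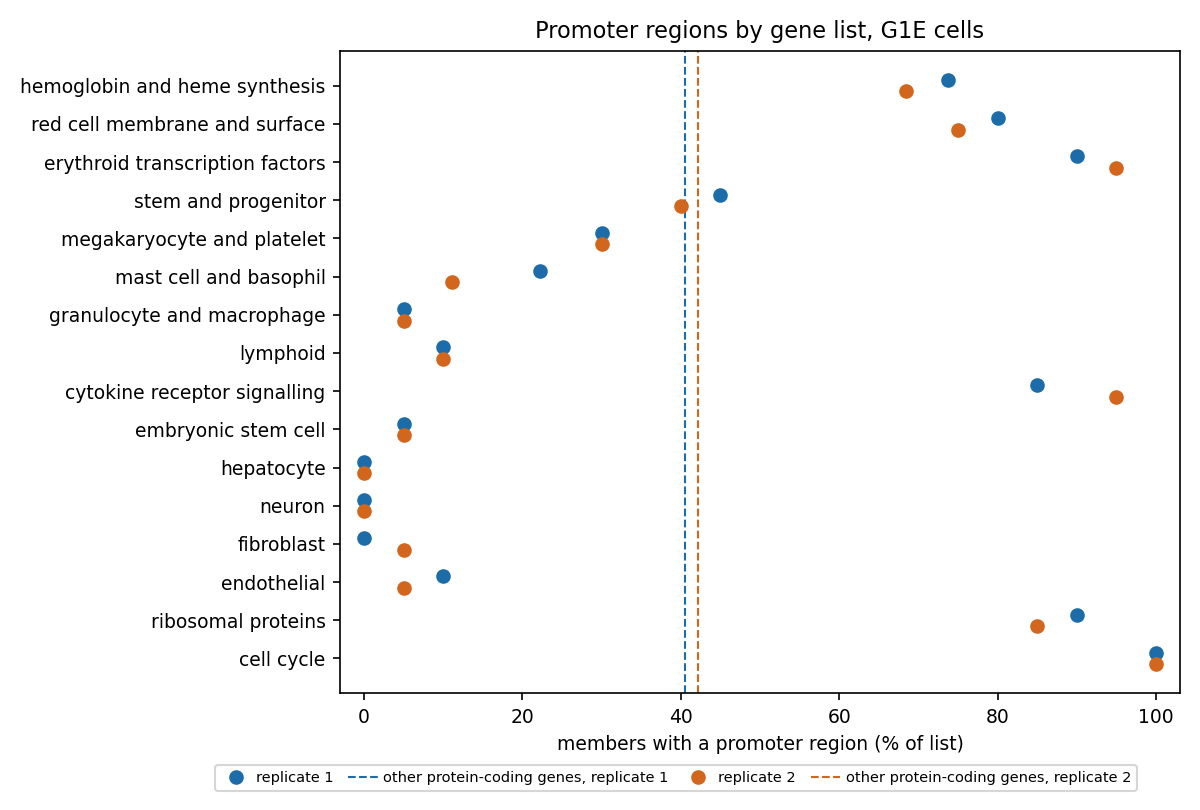
Share of the members of each of 16 gene lists that had a region within 1000 bp of a start site, in percent of the list (horizontal axis), with 1 point per replicate; dashed lines give the share among other protein-coding genes, averaged over the lists. The 3 erythroid lists, cytokine receptor signalling, ribosomal proteins and cell cycle lie to the right of the lines, and the hepatocyte and neuron lists lie at 0 in both replicates.

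All 3 erythroid lists exceeded the other protein-coding genes, of which 40.5% in replicate 1 and 42.1% in replicate 2 had a promoter region (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 16 lists). The adjusted exact p was 3.31e-05 and 4.68e-06 for the transcription factors, 0.000812 and 0.00672 for the membrane list, and 0.00617 and 0.0383 for the heme list. Among the stronger 50% of regions these 3 lists no longer passed, with the transcription factors 9.74, the membrane list 12.2 and the heme list 17.1 percentage points above other genes. The cell cycle list, at 100%, and the ribosomal protein list, at 87.5%, exceeded other genes too, so such an excess is not particular to erythroid genes. Each test describes these 2 libraries, since genes are not independent replicates.

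Most genes of signalling from the erythropoietin and related receptors had a promoter region. Of 20 cytokine receptor signalling genes, 17 had a promoter region in both replicates, 90% ± 7.07 (SD, n = 2; adjusted exact p = 0.000200 and 4.68e-06). Jak1 had a promoter region at the 99.6 mean percentile of signal (chromosome 4, 101265172 to 101265508; signal 19.4 and 22.3), and Ifngr1, a chain of the interferon gamma receptor, followed at 16.5 and 17.8. Epor, Stat5a, Socs3, Cish and Bcl2l1 also had one in both. Jak2, the kinase bound to the erythropoietin receptor, had none in either list.

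The cell cycle list was open throughout, with 20 of 20 promoters in both replicates (adjusted exact p = 2.25e-07 and 4.92e-07), led by the replication licensing gene Mcm3 (signal 19.7 in both) and Ccna2, which encodes cyclin A2 (15.7 and 16.8). Ribosomal protein genes had 87.5% ± 3.54 (SD, n = 2; adjusted exact p = 3.31e-05 and 0.000322), with a signal of 10.8 and 14.0 at Rps19 and no region at Rpl4 and Rpl10a, although the lenient lists of both replicates held one at Rpl4. Ribosomal promoters are rich in CpG, and against random lists matched on promoter CpG content the adjusted permutation p was 0.0292 and 0.153, so that call was not kept in replicate 2. It was not kept among the stronger 50% of regions either, at 32.3 percentage points above other genes.

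Genes of other lineages were mostly without a promoter region. None of the 20 hepatocyte genes and none of the 20 neuron genes had one in either replicate (adjusted exact p = 9.80e-05 and 9.45e-05 for each list). Ahsg, Camk2a and Dcx are examples, and Afp had one in the lenient lists of both replicates. Embryonic stem cell genes had 1 of 20, Dppa4, in both replicates, while the pluripotency genes Nanog and Sox2 had none and Pou5f1 had one in the lenient list of replicate 1 alone (adjusted exact p = 0.00132 and 0.000604). Fibroblast genes had 0 and 1 of 20, the 1 being Col1a1 (adjusted exact p = 9.80e-05 and 0.000604). Endothelial genes had 2 and 1 of 20, with Sox17 in both and Cdh5 and Cldn5 in neither (adjusted exact p = 0.00618 and 0.000604).

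Among blood lineages, granulocyte and macrophage genes had 1 of 20 in both replicates (adjusted exact p = 0.00132 and 0.000604). That gene was Spi1, which encodes the myeloid and lymphoid factor PU.1 (signal 11.6 and 12.2), while Mpo, Elane, Csf1r and Cebpa had none. Lymphoid genes had 2 of 20, Ebf1 and Lck (adjusted exact p = 0.00618 and 0.00391). Matching on promoter CpG content ended the call for 4 lists with low shares: the adjusted permutation p was 0.106 and 0.0880 for granulocyte and macrophage genes, 0.227 and 0.171 for lymphoid, 0.146 and 0.131 for hepatocyte, and 0.0611 and 0.00880 for endothelial genes. The neuron, fibroblast and embryonic stem cell lists stayed below their matched lists.

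Stem and progenitor, megakaryocyte, and mast cell genes did not pass in both replicates. Of the stem and progenitor genes 42.5% ± 3.54 (SD, n = 2) had a promoter region (adjusted exact p = 0.820 and 1), among them Kit, Runx1, Lyl1, Mllt3 and Etv6 in both, with Cd34, Hoxa9 and Mecom in neither, and Erg in the lenient list of replicate 2 alone. Of the megakaryocyte and platelet genes 30% had one in each replicate (adjusted exact p = 0.398 and 0.390). Nbeal2 and Gp1ba were strongest (signal 10.6 and 12.8, and 10.7 and 10.9), and Vwf and Itgb3 had none. Mast cell and basophil genes had 4 of 18 in replicate 1 and 2 of 18 in replicate 2 (adjusted exact p = 0.171 and 0.00904), with Cd200r3 and Il1rl1 in both. Without replicate 1 this list would be called lower.

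At the fixed set of 20 blood loci, 16 genes had a promoter region in both replicates. At Myb the regions of the replicates lay apart, so a check added after the data were seen, which required the same region in both, gave 15. The 4 exceptions were Gata2, Alas2, Hbb-bt and Hbb-y. At Gata1, on chromosome X, 2 promoter regions were present in both replicates, both in introns and near start sites other than the outermost one. They lay 9.62 kb (7968293 to 7968619; signal 5.47 and 5.64) and 13.8 kb (7964023 to 7964474; 5.23 and 5.93) inside the outermost annotated 5′ end. Distal regions in both replicates lay 6.57 kb inside that end (7971322 to 7971690; signal 6.36 and 10.2) and 15.4 kb upstream of it (7993136 to 7993862; signal 8.35 and 11.3), with a weaker one beside the latter. Accessibility of the locus does not check the Gata1 disruption, since peak lists do not show whether the gene is intact.

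Gata2, which encodes the related factor of stem and progenitor cells, had no region within 1000 bp of a start site. The nearest region in both replicates lay 1.99 kb upstream (chromosome 6, 88191704 to 88192093; signal 4.95 and 6.09), with 2 GATA matches, and another 4.13 kb upstream at a noncoding start site (88189612 to 88189921; signal 7.85 and 4.73). Intergenic regions in both replicates were also listed 77.0 kb upstream (88116366 to 88117448; signal 7.77 and 7.66, with 3 GATA matches) and 69.8 kb upstream (88123905 to 88124337; signal 5.84 and 7.55).

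The beta-globin cluster on chromosome 7 had listed regions at distal elements, and none was listed at the promoters of Hbb-y, Hbb-bh1 or Hbb-bt, which at unknown depth does not show them to be closed. Upstream of the embryonic gene Hbb-y, where the locus control region lies, the 5 nearest regions listed in both replicates were at 6.12, 7.87, 12.7, 17.7 and 24.1 kb. The strongest of these lay 17.7 kb upstream (103870665 to 103871071, intergenic; signal 15.9 and 15.3), followed by the one 24.1 kb upstream (103877046 to 103877495; 12.7 and 15.1). Between Hbb-y and Hbb-bh1, upstream of the latter, lay a further distal region in both replicates (103844550 to 103845155, intergenic, signal 12.1 and 16.1). On the other side of the cluster, 20.8 kb beyond the start of Hbb-bt, lay the strongest region of the locus in both replicates (103792973 to 103793435, intergenic; 19.6 and 16.7). The adult gene Hbb-bs had a promoter region in replicate 1 alone (signal 5.35), although the lenient lists of both replicates held one.

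**Figure D2:**
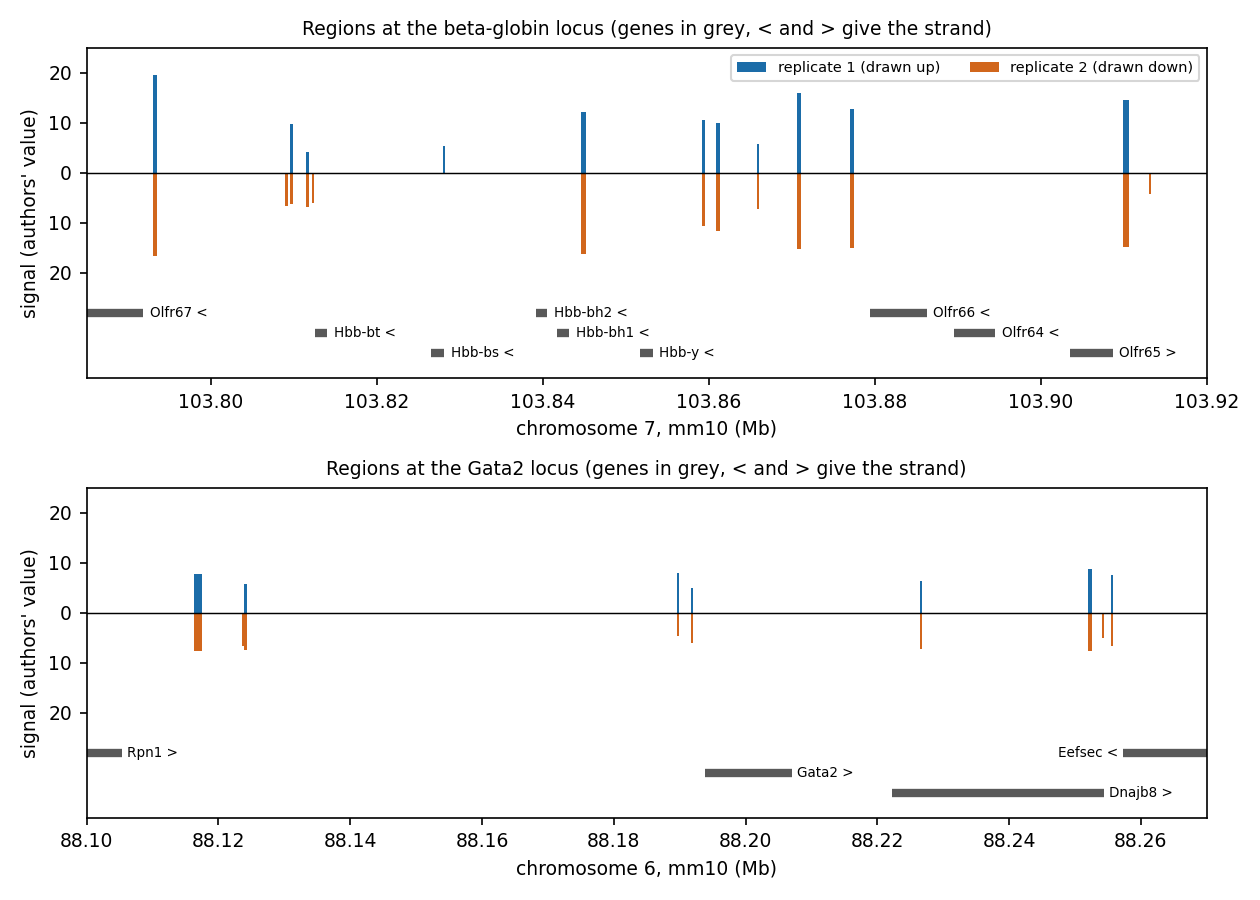
Regions at the beta-globin locus (top, chromosome 7) and the Gata2 locus (bottom, chromosome 6), with position in Mb of mm10 on the horizontal axis; each bar is 1 region as wide as listed, with the authors' signal value as its height, upward for replicate 1 and downward for replicate 2, and grey lines are protein-coding genes. Regions of both replicates stand upstream of Hbb-y, to the right of the gene, and 1.99 and 4.13 kb upstream of Gata2, with none at the start sites of Hbb-y or Gata2.

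At Alas2 on chromosome X, too, the listed regions were away from the start site. Within the gene, 2 intronic regions were among the strong regions of both replicates, 2.51 kb (150549569 to 150550194; signal 14.7 and 18.1, with 3 GATA matches) and 17.5 kb (150564596 to 150565208; 14.5 and 17.1) from the start site. The alpha-globin gene Hba-a1 had a promoter region (signal 11.8 and 11.4) and its strongest distal region 37.8 kb upstream in an intron of Nprl3 (chromosome 11, 32245408 to 32246035; 16.1 and 14.5), where alpha-globin enhancers are known. Zfpm1, which encodes the GATA cofactor FOG1, had 6 distal regions in both replicates within 50 kb, 5 of them in its own introns. Tal1 had 4, the strongest by mean percentile 39.7 kb downstream of its start (chromosome 4, 115095529 to 115096808; 13.2 and 12.8). Runx1 had 5 and Slc25a37 had 4. Kit had 1, in an intron 5.05 kb from its start (chromosome 5, 75579636 to 75580306; 7.39 and 6.23). The 1 distal region near Spi1 lay 21.4 kb upstream in an intron of Psmc3 (chromosome 2, 91060598 to 91061364; 15.2 and 13.2). Klf1 and Tfrc had no distal region in both replicates within 50 kb.

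By their medians, distal regions were most numerous around hemoglobin and heme synthesis genes, followed by cytokine receptor signalling genes, and several lists of other kinds were raised too. The median number of distal regions in both replicates within 50 kb was 3 for the hemoglobin and heme synthesis list and 2 for the cytokine receptor signalling list, against 0 over all protein-coding genes, and each of these medians lay at the 100th percentile of 10000 random lists. The erythroid transcription factor, membrane, stem and progenitor, megakaryocyte, mast cell and cell cycle lists each had a median of 1, at percentiles of 98.3 to 98.6. The endothelial list had a median of 0.5 (percentile 94.7), and the remaining 7 lists had a median of 0. Of the mast cell genes 11 of 18 had a distal region nearby, with 3 each at Cpa3, Cma1 and Il1rl1. The hemoglobin list and the mast cell list were in the top 2.5% of random lists in 7 of 7 settings and cytokine signalling in 6 of 7, while the other 5 lists were in 2 to 5. The count of such lists was 8, and 5 without either replicate. Globin genes share their neighbourhoods, and without the 7 globin genes, a check added after the data were seen, the median of the heme list was 1.5 (percentile 99.9). That is below the median of 2 of the cytokine receptor signalling list, so the first place of the heme list rests on its globin genes. Mast cell genes share their neighbourhoods too: without the 8 members that lie near another, a check also added later, the median was 1 (percentile 96.4), outside the top 2.5%.

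The protein-coding genes with the most distal regions in both replicates within 50 kb were led by 5 with 9 each: Ccr1, Hbb-bh1, Hbb-bh2, Hbb-bs and Zfp217. Ccr1l1, Dapp1, Hbb-y and Smg9 had 8 each, and 3110040M04Rik had 7. Ccr1 and Ccr1l1 are neighbouring chemokine receptor genes on chromosome 9 and, like Zfp217 on chromosome 2, had no promoter region in either replicate. Dapp1, Smg9 and 3110040M04Rik had one in both.

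The GATA motif was the most frequent of the tested motifs at distal regions. It occurred in the 200 bp around 7018 of 10789 distal summits in replicate 1 (65.0%) and 7317 of 11618 in replicate 2 (63.0%), against 32.3% and 31.9% of control windows 2000 bp away, a ratio of 1.99. The combined motif of a CTG followed by GATAA after 7, 8 or 9 bases, bound by complexes of GATA factors and TAL1, occurred at 16.2% and 15.8% of distal summits, 9.38 times the control. Both passed the threshold of 0.05 for the adjusted p in both replicates by two-sided Fisher's exact test over 20 motifs and 2 classes.

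Motifs of other blood regulators were raised at distal summits as well. The NF-E2 motif occurred at 2.86% ± 0.00452 (SD, n = 2), 12.3 times the control (adjusted exact p = 2.97e-62 and 4.07e-70), and the AP-1 motif at 11.5% ± 0.217, 3.62 times (3.80e-123 and 8.38e-143, exact). The AP-1 share includes every window with an NF-E2 match. RUNX had 7.21% ± 0.0332, 3.32 times the control (adjusted exact p = 3.23e-71 and 5.94e-77), and PU.1 had 6.09% ± 0.155, 5.32 times (4.74e-87 and 1.44e-102, exact). The KLF1 motif had 14.5% ± 0.157, 2.46 times the control, the E-box 34.5% ± 0.257, 1.53 times, MYB 27.3% ± 0.0668, 1.35 times, and STAT5 4.44% ± 0.108, 1.65 times. CTCF, the factor of insulators and loop anchors, was found at 4.31% ± 0.645 of distal summits and 0.112% of control windows (adjusted exact p = 3.00e-106 and 1.42e-148). Motifs that stand for other cell types did not pass at distal summits: HNF4 of liver was at 0.218% against 0.281%, MEF2 of muscle and neurons at 0.356% against 0.358%, while the POU-SOX string of embryonic stem cells had 0 matches in summit and control windows alike and so could not be called either way.

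**Figure D3:**
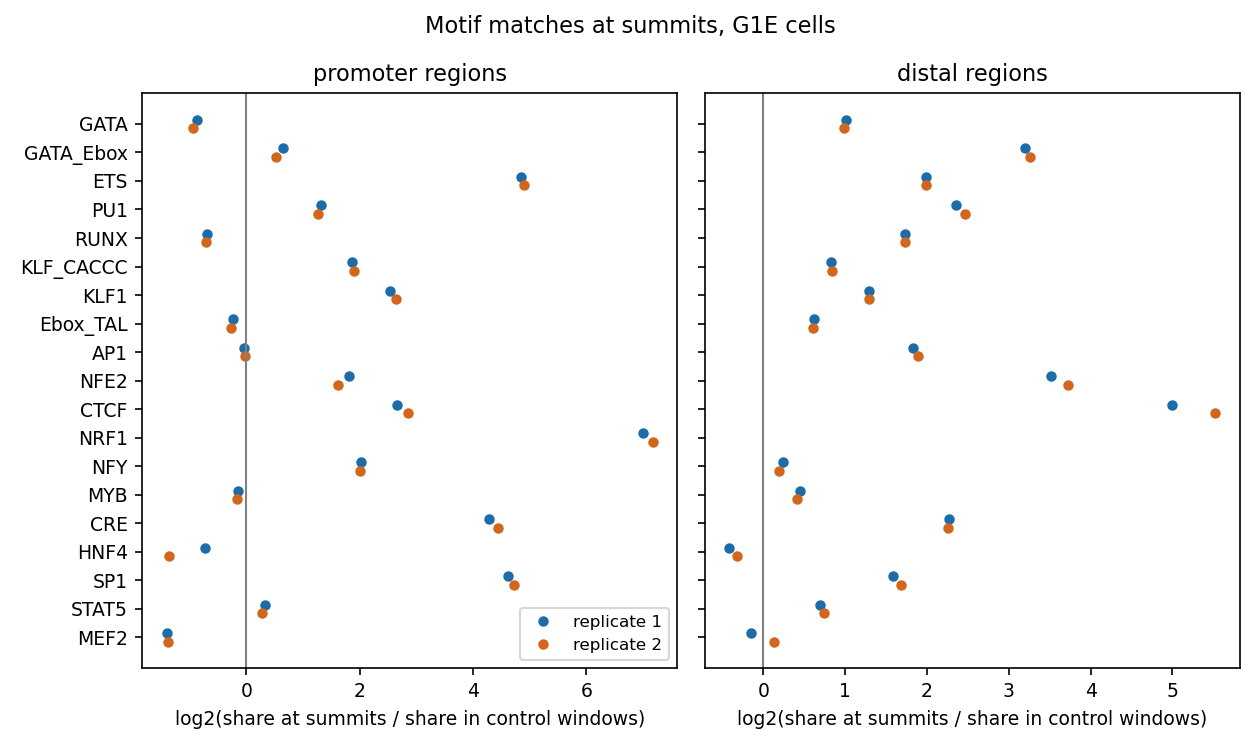
Log2 ratio of the share of 200 bp summit windows with a motif match to the share of control windows (horizontal axis), for promoter regions (left) and distal regions (right), with 1 point per replicate for each motif; pairs with no match in the control windows are left out, and the 2 panels have different scales. GATA is above 0 at distal regions in both replicates and below 0 at promoters, and ETS, SP1, CRE and NRF1 have their largest ratios at promoters.

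The motifs raised at promoter and distal summits overlapped and differed in degree. At promoter summits ETS was found at 15.8% ± 0.140 (SD, n = 2), 29.3 times the control, SP1 at 16.1% ± 0.370, 25.4 times, CRE at 3.34% ± 0.131, 20.6 times, and NFY at 24.3% ± 0.225, 4.04 times. NRF1 was at 1.39% ± 0.0621 of promoter summits and at 1 control window in each replicate. The KLF1 motif was at 39.2% ± 0.190, 5.99 times the control. This share includes every window with an SP1 match, since the KLF1 string matches all SP1 sites, so it does not single out KLF1. At promoters CTCF (6.79 times the control), NF-E2 (3.26), PU.1 (2.44) and STAT5 (1.23) also passed in both replicates, as did the combined CTG-GATAA motif (2.76% against 1.84%). So did CRE (4.79), ETS (3.98), SP1 (3.10) and NFY (1.16) at distal summits, where NFY turned lower with GC-matched or shuffled controls. GATA was lower at promoter summits than in control windows, 16.9% ± 0.275 against 31.6% (adjusted exact p = 7.29e-118 and 4.08e-142). That direction turned with controls of the same GC content, where the log2 ratio was 0.63 in place of −0.91, so the lower value goes with the base composition of promoters. Part of the promoter ratios does too: the log2 ratio of ETS was 4.86 against neighbouring windows, 3.48 against GC-matched and 2.51 against shuffled ones, and that of SP1 was 4.66, 1.66 and 3.00. Both stayed past the threshold under these controls.

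Tested directly, 18 of 20 motifs differed between distal and promoter summits in both replicates. This compared shares with no control for base composition, so part of a difference can come from composition. MEF2, for example, was at 0.356% of distal summits against 0.358% of their control windows. Higher at distal regions were GATA (65.0% against 17.1% in replicate 1 and 63.0% against 16.7% in replicate 2), AP-1, PU.1, the E-box, MYB, STAT5, MEF2, the combined CTG-GATAA motif (16.2% against 2.87% in replicate 1 and 15.8% against 2.65% in replicate 2; adjusted exact p = 6.17e-248 and 4.24e-265), RUNX (7.18% against 1.35% and 7.23% against 1.38%; 2.03e-100 and 2.20e-106, exact), NF-E2 (2.86% against 0.438% and 2.86% against 0.454%; 1.87e-45 and 5.99e-47, exact) and CTCF (3.86% against 0.990% and 4.77% against 1.21%; 5.79e-42 and 1.65e-55, exact). Higher at promoters were ETS, SP1, CRE, NRF1, NFY and both KLF motifs. HNF4 did not differ in both replicates, and the POU-SOX string had no match.

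The strongest promoter regions in both replicates were at Gm20594 (chromosome 6, 79818076 to 79818415; signal 24.0 and 25.3), Ltn1, Trim21, Pdcl3 and Pik3c3. Ltn1 encodes a ubiquitin ligase of stalled ribosomes and had a signal of 25.6 and 23.6 (chromosome 16, 87432376 to 87432850). The 5 strongest distal regions had a higher signal than the 5 strongest promoter regions in both replicates. The first was intergenic, 13.0 kb from the start of Abcb11 (chromosome 2, 69355472 to 69355729; signal 47.4 and 46.9), and the second was in an intron of Gnb1l (chromosome 16, 18533127 to 18533396; 36.5 and 41.4). The others lay in intergenic sequence nearest to Pak3 (chromosome X), Nxph1 (chromosome 6) and G6pd2 (chromosome 5), with signals between 30.9 and 37.2. The region at Gm20594 and those nearest to Abcb11, Nxph1 and G6pd2 match the mitochondrial genome over 129 to 383 bp.

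**Figure D4:**
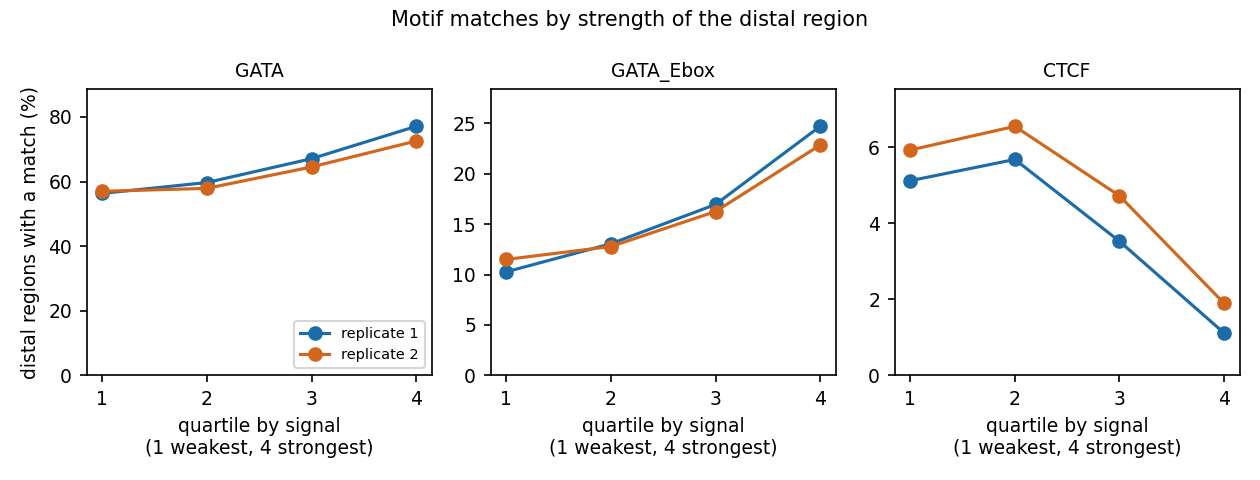
Share of distal regions with a match to the GATA, combined CTG-GATAA and CTCF motifs in percent (vertical axis) by quartile of signal within a replicate (horizontal axis, 1 weakest to 4 strongest), with 1 line per replicate and separate vertical scales. GATA went from 56.3% to 77.1% in replicate 1, and CTCF from 5.11% to 1.11%.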

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

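The tests of both results here were chosen only after the lists were seen, and both concern data that the comparisons do not use. An archived list of the series, which the authors derived from other files than the released lists, held 143526 regions, of which 94317 (65.7%) overlapped no region of the other lists used. Among the 83971 distal regions of these, GATA matches occurred at 36.9% of summits against 35.7% of control windows, and the combined CTG-GATAA motif at 2.48% against 1.95%. CTCF matches occurred at 1.22% against 0.0929%. Archived regions that overlapped the other lists had GATA matches at 51.5%, against 32.5% of their control windows.

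Peaks on unplaced scaffolds numbered 207 in the ranked lists of both replicates together, 106 in replicate 1 and 101 in replicate 2, on 17 scaffolds in each. The thresholded lists held 0 of them. Their highest signal was 24.7 and 27.3, against 47.4 and 46.9 on the assembled chromosomes.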

How the results depend on the processing

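The list over both replicates, the means, the same-region count and the mast cell check were chosen only after the data were seen. The counts and shares follow the threshold. With the lenient lists there were 37260 regions per replicate, 67.6% overlapped, 32.4% were in 1 replicate alone and 32.5% were at promoters. In the stronger 50% there were 10954 regions by construction, 55.1% at promoters, and 7 of the 20 fixed loci kept a promoter region in place of 16. In the main lists, 15 of these 16 had the same region in both replicates. Overlap was 76.0% when reciprocal and 74.8% between summits, from 81.0%. The replicate correlation was 0.888 past the IDR threshold and 0.884 on the log2 scale. That threshold keeps regions that rank alike in the replicates, so the filter itself can raise the first value. The promoter share was 41.8% within 500 bp, 48.8% within 2000 bp, 48.9% with start sites of every biotype, 37.5% with 1 start site per gene, and 47.5% in the list over both replicates, an alternative added later. Of 13 gene lists called, 8 were called with CpG matching. The number of lists with a neighbourhood median in the top 2.5% of random lists was 8, and it was 5 without either replicate, 4 in the stronger 50% and 3 within 20 kb. Without members near each other, the mast cell list fell from the 98.3 to the 96.4 percentile. Against GC-matched windows, 4 motifs that were lower at promoters turned to log2 ratios above 0 (GATA 0.63, RUNX 0.69, MYB 0.51, MEF2 0.83) and NFY at distal regions to −0.22. Against shuffled windows, GATA (0.39), RUNX (1.18), the E-box (0.025) and MEF2 (1.59) at promoters and NFY at distal regions (−0.16) turned. Both controls share the base composition of the windows. The cause of the other changes was not tested. The GATA log2 ratio at distal regions stayed between 0.70 and 1.43 in every setting run. Overlap and correlation have no value without 1 of the replicates. No paired analysis was possible because the series has 1 group. Depth is unknown, so absence from a list limits every count.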

Other observations

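Of the tests here, that of the identity of matching mitochondrial sequence was chosen only after the strongest regions had been seen. The strongest distal regions were those richest in GATA matches. From the weakest to the strongest quartile of distal regions by signal, the share with a GATA match went from 56.3% to 77.1% in replicate 1 and from 1655 of 2905 to 2107 of 2904 regions (72.6%) in replicate 2. The combined CTG-GATAA motif went from 10.3% to 24.7% and from 11.5% to 22.8%. CTCF went the other way, from 5.11% to 1.11% and from 5.92% to 1.89%.

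The spacing inside the combined motif was counted as a hypothesis of a composite site. Among 21 spacings between CTG and GATAA, 9 bases was the most frequent in both replicates, at 918 and 982 distal summits (8.51% and 8.45%), 3.69 times the median over spacings, 8 bases came next at 5.91% and 5.90%, and 10 bases after that at 3.16% and 3.21%. The spacing of 7 bases, also part of the combined motif, occurred at 242 summits in each replicate, below the medians of 249 and 266. In control windows the spacing of 9 bases occurred at 0.603% and 0.586%. These values are consistent with a composite site of a preferred spacing of 8 or 9 bases, as TAL1 and GATA factors are known to bind, and the ratio of 3.69 was past the bound of 3 set before it was computed, although the enrichment of the combined motif was already known. Which factor is bound was not measured.

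A candidate explanation for GATA matches at distal summits of cells without GATA1 is another factor bound there, such as GATA2. Match density within 50 bp of the summit was at least 2.75 times that farther out in both replicates, as binding at the summit predicts. The excess of matches in the 200 bp around summits was already known, so this ratio is not independent of it. Base composition is argued against, since the share was 2.15 times that in dinucleotide shuffles of the same windows in the lower of the replicates, and so are weak regions near the threshold, since the strongest quartile exceeded the weakest by at least 15.6 percentage points. Whether any GATA factor occupies these sites, and which, stays open, since binding was not measured and no biological alternative was tested.

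Of the 20 strongest regions, 7 (35%) matched the mitochondrial genome over 100 bp or more, against 28 of all 17425 regions in both replicates and 0 of the same regions in 1 random placement. Among those 28, the 8 with 95% identity or more had a median percentile of signal of 99.96, but 5 of these belong to the 20 chosen for their strength, and the 3 outside it had a median of 53.3, so whether identity to mitochondrial DNA goes with signal cannot be told. Of the 13 without such a match, 1 (7.69%) held a match of 30 bp or more, but these were set apart for lacking a match, so this decides nothing. The median number of exact nuclear copies of the 50 bases at the summit was 1, below the bound set in advance for sequence in several copies. Of the 20, 6 had more than 1, against 12 of 200 other regions. That count left out the mitochondrial genome and inexact copies, so it speaks only against exact nuclear copies in most of the 20. CTCF sites are argued against, with 0% of the 20 holding the motif. Nuclear copies of mitochondrial DNA and other sequence in several copies stay open, as does what sets the regions apart, and no biological explanation was tested.

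Promoter regions on chromosome X had a higher median signal in the lenient lists than those of any of the autosomes, with the higher ratio to the autosomal median 1.18, in replicate 2, and with 334 and 362 regions. The line is male per the labels, and the lower signal that 1 copy of the X chromosome predicts, if signal follows copy number, was not seen. The medians cover listed regions only and leave out any that fell below the threshold, so the source of the higher value stays open. The value says nothing about the number of X copies. Among autosomes the highest ratio was that of chromosome 1 in both replicates, 1.07 in the lower of them, inside the bound set in advance for equal copy number. That bound was wrong, a judgement made after the X value was seen: the single X did not read lower, so the signal value may not follow copy number, and an extra autosome cannot be told apart from equal copies.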
